A study of Macaca radiata with 6 samples.

How the data were processed

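Gene expression was measured on 6 Affymetrix arrays of the Rhesus chip type, per the scanner experiment files, each hybridised with biotin-labelled total RNA from the corpus luteum of bonnet monkeys (Macaca radiata). Of these, 3 arrays carried the group given prostaglandin F2-alpha (PGF2alpha) and 3 the group given phosphate-buffered saline as vehicle, with groups and replicate numbers (1 to 3 and 4 to 6) taken from the sample titles. The labels give 3 monkeys per group but do not say which array came from which animal, so p-values measure the spread between these 6 samples. The probe sequences were those of another macaque species, so a probe set that mismatches a bonnet monkey transcript would read low in both groups.

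The deposited values are linear signal intensities per probe set made with Microarray Suite 5.0 (MAS5), per the labels and the submitters' processing notes, and no version is given in the sources used here. The trimmed mean of the deposited intensities, leaving out 2% at each end, was 500.0 on all 6 arrays, so the authors' table was taken as already scaled between arrays and was used without further normalization, by a rule fixed before the data were examined. The scanner experiment files, deposited by the authors for each array, hold other settings of the fluidics station and scanner and no expression value. They placed the arrays in 2 hybridisation runs. Run 1 held PGF2alpha replicates 1 and 3 and vehicle replicates 5 and 6, and run 2 held PGF2alpha replicate 2 and vehicle replicate 4. Detection calls were not used here, so no level of a gene could be set against background.

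The table held 52865 probe sets, of which 99 were controls and entered no test between groups other than the check of RNA quality. Gene symbols came from a platform annotation table that can be old. It gave 1 symbol for 24969 probe sets, several for 361 and none for 27535 (52.1%), which are unnamed here. Genes were named only from probe sets with 1 symbol. No genome was used, so no coordinates are given. A pair of symbols in the gene lists was renamed to those of the annotation (HBA1 to HBA and FCGR3A to FCGR3) after the annotation had been seen.

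Values were taken as log2(signal + 40), where 40 is the 25th percentile of all values in the table, so fold changes are on the log2(signal + 40) scale and understate the change of low genes. A probe set was tested if it lay at or above the median of its array in at least 3 of the 6 arrays, which left 26944 probe sets. A gene was represented by its tested probe set of highest mean over all 6 arrays, which gave 9980 genes. Group differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, with no covariate), two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. A second count asked in addition for a change of at least 2-fold. Values of named genes are means of the deposited signals ± SD over the 3 arrays of a group.

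In all, 28 gene lists covering luteal function, cell types and stress responses were written before the data were examined. They held 647 genes, of which 463 were named on the array and 411 were tested. Lists with at least 5 tested genes were tested against all other genes with camera (preset correlation between genes of 0.01, two-sided), with Benjamini-Hochberg adjustment over the 26 lists tested. The test was repeated with a correlation estimated for each list, and fry was run beside it, which tests whether the genes of a list move one way on balance and makes no comparison with other genes. RNA quality was compared through the ratio of 3-prime to 5-prime control probe sets of beta-actin and GAPDH with an exact permutation test, whose smallest p for 3 against 3 arrays is 0.1.

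Named genes followed a rule fixed before the data were examined. It took the 8 genes with the largest increase and the 8 with the largest decrease among those past the threshold whose groups did not overlap, 18 genes of luteal function whatever their values, and the 2 to 4 members of smallest p of each list. Of those 18 genes, 8 had a tested probe set and 10 had no probe set named here, so the latter are not analysed here. A gene outside the rule is said to have been chosen after its values were seen.

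On simulated data built from these 6 arrays, with 200 of 26944 probe sets changed, the same test recovered 32% of 2-fold and 75% of 4-fold changes, with 4 false calls among 111, and it made 0 calls where nothing had been changed. A shifted list was found and 0 of 27 other lists were called. The simulated noise was independent between probe sets and the lists were drawn at random. The simulation therefore cannot show how the list test behaves where the genes of a list move together. The number of arrays limits the precision. The alternatives were quantile normalization, scaling to one median, pseudocounts of 10 and 160, no filter or a filter at the 70th percentile, eBayes without trend or with robust estimation, array weights, leaving out probe sets that can cross-hybridise (those whose names end in _x_at or _s_at), the mean over a gene's probe sets, leaving out each array, and the hybridisation run as a block. A test within run 1 alone was added after the data had been seen.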

Results

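The series profiled the corpus luteum, the ovarian gland that secretes progesterone after ovulation, in bonnet monkeys on day 10 of the luteal phase. Monkeys received 3 intramuscular injections of PGF2alpha, a prostaglandin that induces regression of the corpus luteum, at 59 µg/kg, or vehicle, and the tissue was collected 24 h later. Each group had 3 arrays. The median signal per array lay between 115 and 134 and the highest signal between 62373 and 76997. The comparison asks which transcripts of the primate corpus luteum differ after PGF2alpha.

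PGF2alpha was followed by a shift of gene lists of macrophages, cytokines and matrix to higher levels and of steroid synthesis to lower levels, by a list test whose calls were all lost with an estimated correlation between genes. COL10A1, which encodes the collagen of hypertrophic cartilage, had the largest estimated increase among named genes, from 37.9 ± 31.2 to 13400 ± 11800 (SD, n = 3), a log2 fold change of 6.88 (SE 0.779, adjusted p = 0.0054). Its vehicle signals lay around the pseudocount of 40 and were not shown to be above background, so the size of this fold is uncertain and ran from 5.49 to 7.94 over the alternatives. S100A9 and S100A8, the subunits of calprotectin in neutrophils and monocytes, rose by 5.66 (SE 0.487, adjusted p = 0.00165) and 5.00 (SE 0.407, adjusted p = 0.00142) on the log2 scale. CCL18, a chemokine of macrophages and dendritic cells, rose from 378 ± 56.9 to 9257 ± 2980 (SD, n = 3), by 4.44 (SE 0.225, adjusted p = 0.000195). CYP3A4, a cytochrome P450 that oxidises drugs and steroids, showed the largest decrease, from 16130 ± 11300 to 718 ± 656 (SD, n = 3), a log2 fold change of -4.39 (SE 0.694, adjusted p = 0.0123).

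The other largest increases were in CCL17, a ligand of the receptor CCR4 (log2 fold change 5.33), MYH8, the perinatal skeletal myosin heavy chain (4.51), ANKRD1, a nuclear ankyrin-repeat protein of muscle (4.31), and CP, the copper-carrying ferroxidase ceruloplasmin (4.01), with adjusted p from 0.00278 to 0.0244. The vehicle signals of COL10A1, MYH8 and ANKRD1 were the lowest of these, with means of 37.9, 21.6 and 7.15, so the folds of MYH8 and ANKRD1 are uncertain in size as well. The vehicle means of S100A9 (73.1), S100A8 (97.9), CCL17 (75.9) and CP (79.0) lay below the median signal of every array. Their folds are therefore uncertain in size too. The other largest decreases were in PBX3 (-3.87), a homeodomain transcription factor, the small GTPase ARL14 (-3.13), the chloride channel protein CLIC5 (-2.56), the unnamed loci LOC706528 (-2.48) and LOC721819 (-2.40), the tight-junction protein CLDN3 (-2.33) and RGN, a calcium-binding protein (-2.28), with adjusted p from 0.00963 to 0.0348. Among the called genes named here or in the observations that follow, 9 were read from probe sets that can cross-hybridise, namely S100A9, CYP3A4, PBX3, TM7SF2, PGRMC1, LCN2, GNLY, GSTA3 and FLNA. For S100A9, CYP3A4, TM7SF2, LCN2 and FLNA no other kind of probe set was tested. Of PBX3, 1 of its 2 other probe sets had the opposite sign (0.30, adjusted p = 0.291). In PGF2alpha replicate 3 the 16 genes of largest change lay nearest to the vehicle arrays of the 3 treated arrays in all but CCL18.

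**Figure D1:**
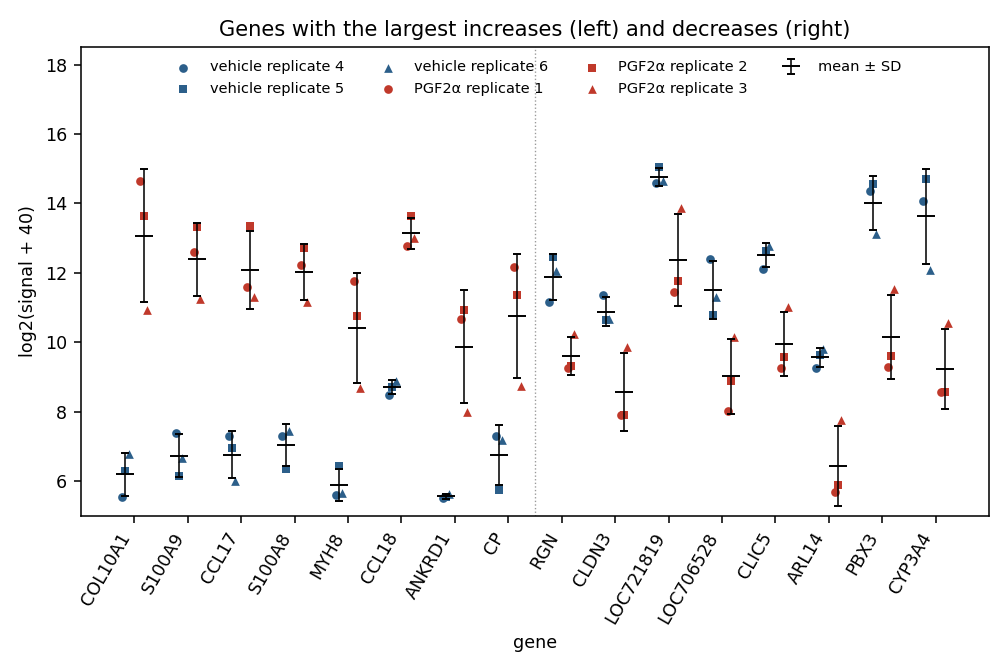
Signal of the 8 genes with the largest increases and the 8 with the largest decreases after PGF2alpha, as log2(signal + 40) on the vertical axis, with 1 symbol per array and bars for the mean ± SD of each group (n = 3). In each of these genes all 3 PGF2alpha arrays lay on one side of all 3 vehicle arrays.

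Of 26944 tested probe sets, 1351 (5.01%) passed an adjusted p of 0.05, 815 of them higher and 536 lower after PGF2alpha, and 799 of these changed at least 2-fold (525 higher, 274 lower). At gene level 606 of 9980 genes passed, 375 higher and 231 lower. Of the called probe sets 380 are unnamed here. All 3 treated arrays lay on one side of all 3 vehicle arrays in 7211 probe sets (26.8%), against 10% by chance. The number of called probe sets was 364 without PGF2alpha replicate 1, 223 without replicate 2 and 1903 without replicate 3, and 619, 633 and 435 without vehicle replicates 4, 5 and 6. Changes of at least 2-fold numbered 334, 207 and 1254 without PGF2alpha replicates 1, 2 and 3 and 522, 499 and 405 without vehicle replicates 4, 5 and 6, and called genes numbered 153, 99, 278, 280 and 193 without PGF2alpha replicates 1 and 2 and vehicle replicates 4, 5 and 6.

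**Figure D2:**
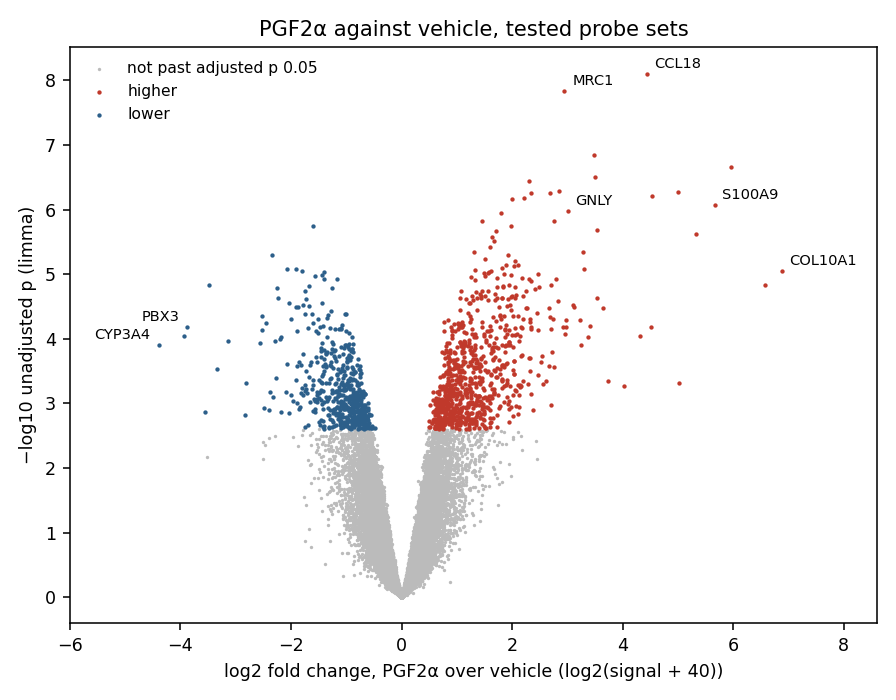
Each point is 1 of the 26944 tested probe sets, with the log2 fold change of PGF2alpha over vehicle on the horizontal axis and the -log10 of the unadjusted limma p on the vertical axis. Red and blue points are the 815 higher and 536 lower probe sets past an adjusted p of 0.05, and the largest increases exceed the largest decreases in size.

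Macrophage and monocyte markers shifted higher as a list. Of 17 tested markers, 8 rose and 0 fell (12 and 0 adjusted over the list alone), with a median log2 fold change of 1.05 (camera adjusted p = 5.61e-08). MRC1, the macrophage mannose receptor, rose from 1167 ± 59.5 to 9363 ± 1770 (SD, n = 3), by 2.95 on the log2 scale (adjusted p = 0.000195). The scavenger receptor MARCO rose by 2.67 (adjusted p = 0.00736), the endotoxin co-receptor CD14 by 1.23 (adjusted p = 0.0212) and the complement receptor VSIG4 by 1.34 (adjusted p = 0.0235). The vehicle mean of MARCO (60.4) lay below the median signal of every array, so its fold is uncertain in size. The list's call was lost with an estimated correlation (adjusted p = 0.254). Its median was 1.24 within run 1 and 0.868 within run 2.

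The list of cytokines and chemokines shifted in the same direction, with 4 of 16 tested genes higher and 0 lower (6 and 1 adjusted over the list alone), a median of 0.946 and a camera adjusted p of 0.000227 (adjusted p = 0.254 with an estimated correlation). Its medians were 0.533 and 1.47 within runs 1 and 2. The interleukin-1 receptor antagonist IL1RN rose by 3.11 (adjusted p = 0.00736). The monocyte chemoattractants CCL2 and CCL8 rose by 2.32 (adjusted p = 0.00899) and 1.44 (adjusted p = 0.00648), and CCL5 rose by 1.81 (adjusted p = 0.0218). The fold of CCL5 is uncertain in size, as its vehicle mean (86.6) lay below the median signal of every array. Of 10 neutrophil markers named on the array 4 passed the brightness filter, and all 4 rose, with a median of 3.59. They were the calprotectin genes, the gelatinase MMP9 (2.18, adjusted p = 0.0142) and the siderophore-binding LCN2 (1.34, adjusted p = 0.0441), and these are too few for a list test. S100A8, S100A9 and MMP9 passed the filter only through the treated arrays, with vehicle means of 97.9, 73.1 and 141. Their selection by the filter therefore favoured a rise. The other neutrophil markers named on the array stayed below the filter. Without the filter the shift of the neutrophil list was 1.59 (camera adjusted p = 0.000188 with the preset correlation). An estimated correlation, with which all other list calls were lost, was not run for it. Of 8 tested T, NK and B lymphocyte markers only GNLY, the cytolytic protein granulysin, passed. It rose by 3.00 (adjusted p = 0.00186), though its other probe set read 0.47 (adjusted p = 0.232). GZMA had a log2 fold change of -0.85 (adjusted p = 0.0584), and the lymphocyte list was not called (camera adjusted p = 0.326). Red cell markers numbered 4 tested, also too few for a test, with HBB at -0.91 (adjusted p = 0.151) and HBA at -0.23 (adjusted p = 0.755). ALAS2 was at 0.21 (adjusted p = 0.784) and PF4 at 0.11 (adjusted p = 0.893).

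Steroid synthesis genes shifted lower as a list. Of 16 tested, 2 fell and 1 rose, and adjusted over the list alone 10 fell and 1 rose, with a median log2 fold change of -0.632 (camera adjusted p = 0.00232, adjusted p = 0.371 with an estimated correlation). STAR, which carries cholesterol to the inner mitochondrial membrane, fell from 63400 ± 7410 to 40200 ± 8850 (SD, n = 3), a log2 fold change of -0.67 (SE 0.163, adjusted p = 0.0497). CYP17A1, which makes androgen precursors, fell by 1.46 (adjusted p = 0.0299). The member that rose was TSPO, the mitochondrial translocator protein, which is also abundant in macrophages (0.92, adjusted p = 0.0257, with its other probe set at 0.10 and adjusted p = 0.88). Aromatase CYP19A1 (-1.51, adjusted p = 0.0694), HSD17B1 (-1.62, adjusted p = 0.0533), HSD3B2 (-1.09, adjusted p = 0.172) and the inhibin alpha subunit INHA (-0.40, adjusted p = 0.171) did not pass. CYP19A1 did pass with the run as a block (adjusted p = 0.0494), with array weights (adjusted p = 0.0326) and without PGF2alpha replicate 3 (adjusted p = 0.00116), and HSD3B2 without PGF2alpha replicate 3 (adjusted p = 0.019). The call for STAR was lost without each array other than PGF2alpha replicate 3, with adjusted p of 0.159, 0.169, 0.0983, 0.123 and 0.116 without PGF2alpha replicates 1 and 2 and vehicle replicates 4, 5 and 6, and 0.00822 without PGF2alpha replicate 3. It was also lost with the run as a block (adjusted p = 0.0572), and over all alternatives the adjusted p for STAR ran from 0.00822 to 0.249. The list's median was -0.612 within run 1 and -0.641 within run 2, and it was -0.301 in PGF2alpha replicate 3 against -0.853 and -0.708 in replicates 1 and 2.

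The list of cholesterol synthesis and uptake shifted lower and that of cholesterol efflux higher. In the synthesis list 2 of 15 genes fell and 0 rose (3 and 0 adjusted over the list alone), with a median of -0.283 (camera adjusted p = 0.0286, adjusted p = 0.503 with an estimated correlation). The squalene synthase gene FDFT1 fell by 0.79 (adjusted p = 0.0346) and the sterol reductase TM7SF2 fell by 1.40 (adjusted p = 0.0497), while STARD4 stood at -0.66 (adjusted p = 0.0973). This list was not called without PGF2alpha replicate 1 (adjusted p = 0.0565) or vehicle replicate 5 (adjusted p = 0.196), with the stricter filter (adjusted p = 0.0557), with array weights (adjusted p = 0.0655) or by fry (adjusted p = 0.148). Without probe sets that can cross-hybridise its shift against all other genes went from -0.321 to -0.198 and the call was lost (adjusted p = 0.177). Its medians within runs 1 and 2 were -0.382 and -0.195. Targets of the liver X receptors and efflux genes shifted higher, with 2 of 10 genes higher and 0 lower (4 and 0 adjusted over the list alone), a median of 0.358 and a camera adjusted p of 0.00171 (adjusted p = 0.254 with an estimated correlation). The medians within runs 1 and 2 were 0.445 and 0.343. Lipoprotein lipase LPL rose by 1.94 (adjusted p = 0.00589), with 2 of its 3 other probe sets of opposite sign, and the lysosomal cholesterol carrier NPC2 rose by 0.88 (adjusted p = 0.0276). SREBF1 (0.90, adjusted p = 0.0501) and NR1H3 (0.71, adjusted p = 0.0831) did not pass, though the other probe set of SREBF1 was called in the same direction (0.65, adjusted p = 0.0488) and SREBF1 gained a call under 9 of 19 alternatives.

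Among 10 tested gonadotropin and hormone receptors, 1 fell and 0 rose, and the list was not called (camera adjusted p = 0.244). The gene that fell was PGRMC1, a membrane protein associated with progesterone signalling, by 0.73 (adjusted p = 0.019), and the adiponectin receptor ADIPOR2 stood at -0.52 (adjusted p = 0.128). Of 8 genes of prostaglandin synthesis, transport and reception, thromboxane synthase TBXAS1 rose by 0.89 (adjusted p = 0.0354) and TBXA2R did not pass (-0.56, adjusted p = 0.156). That list was not called either (camera adjusted p = 0.532).

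Lists of matrix and protease genes shifted higher. In the fibroblast and collagen list 5 of 21 genes rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.246 and a camera adjusted p of 0.00232 (adjusted p = 0.379 with an estimated correlation). COL6A3, a chain of type VI collagen, rose by 1.13 (adjusted p = 0.0119), tenascin-C (TNC) by 1.63 (adjusted p = 0.0256), versican (VCAN) by 1.19 (adjusted p = 0.0267) and decorin (DCN) by 0.64 (adjusted p = 0.0421). The member that fell, OGN, was chosen after its values were seen (-0.93, adjusted p = 0.0483). Of 22 extracellular proteases and inhibitors 7 rose and 1 fell (9 and 1 adjusted over the list alone), with a median of 0.393 and a camera adjusted p of 0.000321 (adjusted p = 0.254 with an estimated correlation). The collagenase MMP1 rose by 1.91 (adjusted p = 0.00732), the urokinase receptor PLAUR by 2.02 (adjusted p = 0.0086) and urokinase PLAU by 1.54 (adjusted p = 0.00963), and ADAMTS5, also chosen after its values were seen, fell by 1.26 (adjusted p = 0.0417). The fold of MMP1 is uncertain in size, as its vehicle mean (75.9) lay below the median signal of every array. The medians within runs 1 and 2 were 0.255 and 0.472 for the matrix list and 0.515 and 0.373 for the protease list. The medians of single arrays overlapped for the matrix list, with vehicle replicate 5 at 0.229 and PGF2alpha replicate 3 at 0.16.

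Vascular markers did not shift as lists. Of 21 endothelial markers 1 rose and 0 fell (2 and 0 adjusted over the list alone), with a median of 0.0139 (camera adjusted p = 0.562). The gene that rose was the endothelial junction protein CLDN5 (0.90, adjusted p = 0.0266), and endoglin (ENG) did not pass (0.58, adjusted p = 0.0548). Of 19 angiogenic factors the antiangiogenic matrix protein THBS1 rose by 2.16 (adjusted p = 0.0146), ANGPT1 stood at 0.40 (adjusted p = 0.286, with 1 of its 2 other probe sets of opposite sign), and the list was not called (camera adjusted p = 0.679). Of 11 pericyte and smooth muscle markers 0 passed (median 0.0406, camera adjusted p = 0.735), with MYL9 at -0.41 (adjusted p = 0.154) and TPM2 at 0.31 (adjusted p = 0.348), though of the 5 other probe sets of TPM2 2 rose and 2 had the opposite sign. Ovarian stroma and surface epithelium markers (0 of 9, camera adjusted p = 0.933) and granulosa and follicle markers (0 of 5, camera adjusted p = 0.934) gave no call, with UPK3B at -1.09 (adjusted p = 0.0645), NR2F1 at 0.80 (adjusted p = 0.104), KIT at -1.29 (adjusted p = 0.221) and SERPINE2 at 0.33 (adjusted p = 0.233).

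The list of hypoxia and glycolysis shifted higher and those of antioxidant defence and oxidative phosphorylation lower. In the glycolysis list 15 of 20 genes had a positive log2 fold change, and 3 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.314 and a camera adjusted p of 0.00232 (adjusted p = 0.254 with an estimated correlation). These were the glucose transporter SLC2A1 (0.77, adjusted p = 0.0421), pyruvate kinase PKM (0.83, adjusted p = 0.0121) and lactate dehydrogenase LDHA, which rose from 12600 ± 479 to 21510 ± 602 (SD, n = 3), by 0.77 (adjusted p = 0.00932). Of 16 antioxidant genes 3 fell and 0 rose (6 and 2 adjusted over the list alone), with a median of -0.323 and a camera adjusted p of 0.0178 (adjusted p = 0.358 with an estimated correlation). The glutathione transferases GSTA3 and GSTP1 fell by 1.52 (adjusted p = 0.029) and 0.84 (adjusted p = 0.0293), the peroxiredoxin PRDX6 fell by 1.42 from a low signal (adjusted p = 0.0483), and mitochondrial superoxide dismutase SOD2 stood at 1.68 (adjusted p = 0.0611, its other probe set at -0.13). Of 19 oxidative phosphorylation genes 0 passed singly and 5 had a positive log2 fold change, with UQCRC2 at -0.63 (adjusted p = 0.066) and NDUFA4 at -0.47 (adjusted p = 0.182), and the list shifted lower with a median of -0.228 and a camera adjusted p of 0.0286 (adjusted p = 0.578 with an estimated correlation). The antioxidant call was lost without PGF2alpha replicate 1 (adjusted p = 0.0566), with the mean over the probe sets of a gene (0.0543), the larger pseudocount (0.0644), the stricter filter (0.0725) and by fry (0.0655). The oxidative phosphorylation call was lost without PGF2alpha replicate 1 (0.0618) or 2 (0.155) and without vehicle replicate 4 (0.0664) or 6 (0.082), without a variance trend (0.0515), without probe sets that can cross-hybridise (0.0815), by fry (0.204) and within run 1 (0.257). The medians within runs 1 and 2 were 0.282 and 0.354 for glycolysis, -0.261 and -0.535 for antioxidant defence and -0.173 and -0.373 for oxidative phosphorylation. For the last list the medians of single arrays overlapped, with vehicle replicate 5 at -0.0937 and PGF2alpha replicate 3 at 0.00412.

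Interferon-stimulated genes shifted lower as a list. Of 15 tested, 5 fell and 0 rose (7 and 0 adjusted over the list alone), with a median of -0.633 and a camera adjusted p of 0.000541 (adjusted p = 0.358 with an estimated correlation). The antiviral genes ISG15, MX1, IFI44 and IFIT1 fell by 2.07 (adjusted p = 0.0167), 1.82 (adjusted p = 0.0267), 1.60 (adjusted p = 0.00937) and 1.59 (adjusted p = 0.0219). IFI44 fell from 2019 ± 721 to 614 ± 30.1 (SD, n = 3). The list's median was -0.55 within run 1 and -0.284 within run 2. The medians of single arrays overlapped, with vehicle replicate 5 at -0.362 and PGF2alpha replicate 2 at -0.251.

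In the IGF system, 3 of 13 genes rose and 0 fell (5 and 0 adjusted over the list alone), with a median of 0.202 and a camera adjusted p of 0.0286 (adjusted p = 0.254 with an estimated correlation). These were the binding proteins IGFBP6 (0.89, adjusted p = 0.0266), IGFBP4 (0.58, adjusted p = 0.0266) and IGFBP2 (0.67, adjusted p = 0.0363). The call was lost without PGF2alpha replicate 1 (adjusted p = 0.0536) or vehicle replicate 6 (adjusted p = 0.082), and the medians within runs 1 and 2 were 0.138 and 0.329. Of 24 genes of TGF-beta, activin and BMP signalling, 3 rose and 1 fell with no call for the list (camera adjusted p = 0.212). The stress cytokine GDF15 rose by 1.59 (adjusted p = 0.0123), BMP4 by 1.35 (adjusted p = 0.0321) and the receptor ACVR2B by 1.21 (adjusted p = 0.0393), and the BMP target ID1 fell by 1.05 (adjusted p = 0.0341).

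Apoptosis genes were not called as a list (camera adjusted p = 0.0669), with 2 of 23 higher and 1 lower. PMAIP1 and BCL2L11, both encoding proapoptotic BH3-only proteins, rose by 2.33 (adjusted p = 0.0275) and 0.79 (adjusted p = 0.0426), and the executioner caspase gene CASP6 fell by 0.98 (adjusted p = 0.0151). BAX (0.14, adjusted p = 0.668) and BCL2 (-0.22, adjusted p = 0.805) did not pass. This list was called without PGF2alpha replicate 3 (adjusted p = 0.0451), with the mean over the probe sets of a gene (adjusted p = 0.0392) and without the filter (adjusted p = 0.0151). Of 16 immediate early and AP-1 genes 0 passed over all probe sets by their representative probe set (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.743). JUNB was at 0.78 (adjusted p = 0.065), ATF3 at 1.25 (adjusted p = 0.0878), ZFP36 at -0.71 (adjusted p = 0.0899), NR4A1 at -0.88 (adjusted p = 0.271) and FOS at 0.11 (adjusted p = 0.837). The cell cycle list gave 0 of 21 calls and no shift (camera adjusted p = 0.947), with a median of 0.0113 and a mean of -0.00425, so that these differed in sign, and CDKN1A (0.75, adjusted p = 0.0553) and CCND1 (-0.50, adjusted p = 0.312) did not pass. The unfolded protein response list gave 0 of 16 (camera adjusted p = 0.279), with PDIA4 at 0.66 (adjusted p = 0.0551) and PDIA3 at 0.32 (adjusted p = 0.197). Of 16 lysosome and autophagy genes the protective protein gene CTSA rose by 0.66 (adjusted p = 0.0382) and ATG7 fell by 1.31 (adjusted p = 0.0284), with both other probe sets of ATG7 of opposite sign, and that list was not called (camera adjusted p = 0.149).

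**Figure D3:**
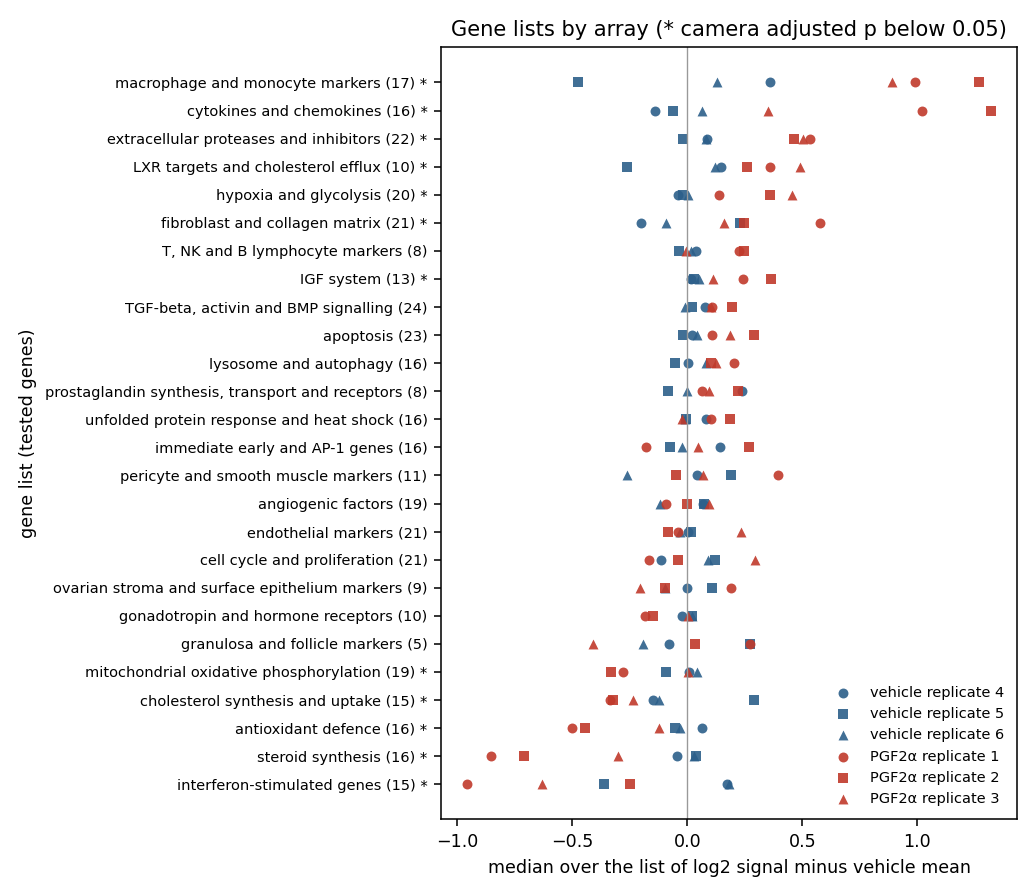
Median over each gene list of the log2 signal of an array minus the mean of the vehicle arrays, on the horizontal axis, with 1 symbol per array, lists ordered by the median log2 fold change and the number of tested genes in brackets. Asterisks mark the 12 lists past a camera adjusted p of 0.05, and for macrophage and monocyte markers the 3 PGF2alpha arrays sit at 0.991, 1.27 and 0.891.

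In all, 12 of 26 lists passed with the preset correlation, 7 higher and 5 lower, against 13 at an unadjusted p of 0.05, and 0 passed with an estimated correlation. By fry 6 lists moved one way on balance, all higher, and steroid synthesis (adjusted p = 0.0722), the matrix list (0.093) and interferon-stimulated genes (0.0687) were among those not called. The mixed form of fry, which asks whether genes of a list change in either direction, called 21 of 26 lists. Among these were lists not called by camera, such as the hormone receptors and TGF-beta signalling (mixed fry adjusted p = 0.00202 for each). A list without a shift is therefore not a list without changes. Counts of genes per list refer to 1 representative probe set per gene. In 10 list members the representative did not pass while another probe set of the gene did, among them KLF6 of the immediate early genes (0.69, adjusted p = 0.124, with 3 of 4 other probe sets called higher, and 0.014 with the mean over its probe sets), and SLC2A3, PDIA4 and PDIA6 with 1 other probe set each called higher. Of the 3 other probe sets of SLC2A3, 2 had the opposite sign. Arrays of one group correlated at 0.953 to 0.961 (PGF2alpha) and 0.953 to 0.967 (vehicle), and arrays of different groups at 0.912 to 0.955. The first principal component held 47.7% of the variance and parted the groups, with PGF2alpha replicates 1, 2 and 3 at 50.3, 56.5 and 13.8 and vehicle replicates 4, 5 and 6 at -42.8, -38.5 and -39.4. PGF2alpha replicate 3 lay nearest to the vehicle arrays.

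RNA quality did not separate the groups by the control ratios. The 3-prime over 5-prime ratio was 1.76 ± 0.0275 (SD, n = 3) after PGF2alpha and 1.76 ± 0.424 after vehicle for beta-actin (exact permutation p = 1, two-sided) and 1.56 ± 0.15 and 1.56 ± 0.16 for GAPDH (exact permutation p = 1). The log2 ratio averaged over both differed by 0.0125 between the groups.

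With the hybridisation run as a block 1343 probe sets were called, of which 1203 were among the 1351. Among the named genes 6 lost their call with the block (STAR, BCL2L11, LCN2, SLC2A1, PRDX6 and FLNA) and 6 gained one (CYP19A1, SREBF1, ATF3, GZMA, CDKN1A and PDIA4). Within run 1 alone (2 arrays per group) 51 probe sets were called, 44 higher and 7 lower, and 50 of these had the same sign in run 2, where each group had 1 array and no test was possible. Of the 500 probe sets of lowest p within run 1, 490 (98%) had the same sign in run 2, against 66.4% of all tested probe sets. Of 80 called genes named here or in the observations that follow, 34, 25 and 71 kept their call without PGF2alpha replicates 1, 2 and 3 and 47, 49 and 41 without vehicle replicates 4, 5 and 6. COL10A1, CCL17, CCL18, S100A8, S100A9, MRC1, MARCO, IL1RN, CCL2, CCL8, MMP1, MMP9, PLAUR, LPL, LDHA and IFI44 were among the 25 that kept it without each array in turn.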

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

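The test within run 1 alone was chosen after the data had been seen. No paired analysis was possible because the groups share no replicate numbers. The counts of 1351 probe sets, 799 at 2-fold or more and 606 genes stayed within 1.5 times under both other scalings, both pseudocounts, the stricter filter, robust estimation, array weights, the run as a block and without probe sets that can cross-hybridise. Without a filter 826 probe sets and 356 genes were called, with more probe sets to adjust over. Without a variance trend the counts were 669 probe sets, 531 at 2-fold and 284 genes, and the cause was not tested. Leaving out 1 array gave 223 to 1903 probe sets, 207 to 1254 at 2-fold and 99 to 864 genes, with fewer samples in each fit. The lowest counts came without PGF2alpha replicate 2 and the highest without PGF2alpha replicate 3. Within run 1 the counts were 51, 51 and 24, from 4 arrays. The share of higher calls was 60.3% and was 60.4% and 60.9% under the other scalings. When 1 array was left out it ran from 54.9% (without PGF2alpha replicate 3) to 74.4% (without PGF2alpha replicate 2), and it was 86.3% within run 1. The number of called lists was 12, with 8 (without PGF2alpha replicate 1) to 13 when 1 array was left out, 6 by fry and 0 with an estimated correlation, which allows for genes of a list moving together. Adjusted p ranged from 2.43e-11 to 0.254 for macrophage markers, 0.000191 to 0.371 for steroid synthesis and 7.53e-06 to 0.358 for interferon-stimulated genes. Oxidative phosphorylation lost its call under 9 of 21 alternatives, cholesterol synthesis under 7, antioxidant defence under 6 and the IGF system under 3, and apoptosis gained one under 3. Reversals concerned only results that had not passed, and the cause was not tested. With the stricter filter the mean shifts of the immediate early, cell cycle and stroma lists were -0.052, 7.59e-05 and 0.145. Without single arrays the cell cycle list ranged from -0.144 to 0.0763, at 0.0763 (PGF2alpha replicate 1), 0.0355 (PGF2alpha 2), 0.0225 (vehicle 5) and 0.00959 (vehicle 6), the pericyte list from -0.0927 to 0.159, below 0 without PGF2alpha 1 (-0.0242) and vehicle 6 (-0.0927), and the endothelial list from -0.0524 to 0.115, below 0 without PGF2alpha 3 (-0.0524) and vehicle 5 (-0.0066). The log2 fold change of FOS was -0.00299 with array weights and -0.0365 to 0.328 when 1 array was left out. That of BCL2 was 0.0318 within run 1 and -0.678 to 0.0304 without 1 array, and that of HBA -0.493 to 0.174. Of 80 called genes named in the text, 41 kept their call under all alternatives that left out no array, the test within run 1 aside. The control ratio difference was 0.0125 with and without a pseudocount. Without a filter the neutrophil list had a shift of 1.59 (camera adjusted p = 0.000188) and the red cell list -0.176 (camera adjusted p = 0.667), both with the preset correlation only. Low signals limit fold sizes, which depend on the pseudocount there, since no detection calls were used.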

Other observations

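The 4 lists first named in this paragraph were written after the data had been seen, and the genes that prompted each were left out of its test. Targets of YAP and of serum response factor, transcription regulators that respond to cell tension, shifted higher as a list after PGF2alpha. Without ANKRD1, PALLD and GSN, which prompted the list, 18 genes had a median log2 fold change of 0.485 (camera adjusted p = 0.000212, adjusted p = 0.114 with an estimated correlation). Of these, 0 fell and 3 rose, namely CCN1 (1.77), CCN2 (1.90, with 2 other probe sets of opposite sign) and FLNA (0.66). Members that did not pass included ACTB (0.05), ACTG1 (-0.01), FLNC (-0.11) and MYL9 (-0.41), so the rise was not shared by all targets. PALLD, an actin-bundling protein, rose by 1.46 and GSN, which severs actin, by 1.32. Genes of alternatively activated macrophages had a median of 0.576 over 10 genes (camera adjusted p = 0.00222, adjusted p = 0.114 with an estimated correlation). None of these passed singly. The macrophage and monocyte list fixed beforehand had a larger median, of 1.05. Camera compared the genes with all others, so it cannot tell alternative activation from a general rise of macrophage transcripts. The genes left out included F13A1 (2.84, its other probe set of opposite sign), PLXDC2 (1.93) and the decoy receptor IL1R2 (3.11, with 1 of its 3 other probe sets of opposite sign). IL1RL1, the interleukin-33 receptor, rose by 3.53. The 3 tested markers of mast cells and basophils beside it had a median of -0.214, below the bound of 0.3 set beforehand. That bound could not decide, because the list left out its called gene IL1RL1 and fell short of the 5 genes asked of a list. Genes of mitochondrial fatty acid and amino acid breakdown had a median of -0.251 over 15 genes without MCCC1 and ECHDC2, both of which fell (camera adjusted p = 0.0168, adjusted p = 0.235 with an estimated correlation), and 0 of the 15 passed singly. The 3 calls among these 4 lists were lost with the estimated correlation. All genes of this paragraph other than ANKRD1 and MYL9 were chosen after their values were seen.

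For the patterns that follow, the tests of mixture, of the whole interferon list without each vehicle array and of the splits of the arrays were written before their results were seen, and the others after. Myeloid markers were higher after PGF2alpha. A loss of luteal cells alone would raise all other cell types alike, but macrophage and monocyte markers exceeded endothelial, pericyte and smooth muscle markers by a median of 1.02 (95% bootstrap interval over genes 0.544 to 1.38). A loss of vascular cells together with luteal cells could give this difference too and was not tested. The intervals over genes in this paragraph hold no spread between animals. Blood left in the tissue would raise the haemoglobin genes HBB and HBA, whose mean log2 fold change was -0.566 (SE 0.303). HBA alone was at 0.174 without PGF2alpha replicate 2. The other tested genes of the red cell list, ALAS2 (0.21) and the platelet gene PF4 (0.11), did not pass. Each run held both groups, and the median was 1.24 (0.709 to 1.36) within run 1, although a first test on the lower of the medians of both runs, with 1 array per group in run 2, had left this open (0.868, -0.00754 to 1.3). An influx of myeloid cells and a change in resident macrophages may both account for the rise and were not told apart by any test here.

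PGF2alpha replicate 3 lay nearer to the vehicle arrays. At probe sets called from the other arrays it stood at a median of 0.547 of the way from the vehicle mean to replicates 1 and 2. A mixture of treated RNA like that of replicates 1 and 2 with vehicle RNA would put raised and lowered probe sets at one linear position. These were 0.435 and 0.609, a difference of -0.174 (-0.224 to -0.134). The probe sets were called from the same arrays that set both ends of this scale, which can move the 2 positions unequally. The interval runs over probe sets alone, so a mixture was not excluded. Vehicle tissue under a wrong label would lie where vehicle arrays do, but these stood at 0.108 to 0.151 at probe sets called without each, and PGF2alpha replicate 1 of the same run correlated less with the vehicle arrays of that run than replicate 3 did, by 0.0264. A smaller response in that animal may also remain as an explanation, which no label allows to be tested, and a sample from outside the series was not tested.

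Interferon-stimulated genes were lower as a list after PGF2alpha. A single vehicle animal with high levels, as the whole cause, would leave the other vehicle arrays at the treated level, but vehicle replicates 4, 5 and 6 lay 0.785, 0.339 and 0.821 above the PGF2alpha mean and above every treated array in 11, 8 and 13 of 15 genes, and the interval over genes of the second highest, 0.216 to 1.56, excluded 0 though not the 0.3 first asked of this test. How much a single animal added stayed open, since the medians without vehicle replicates 4, 5 and 6 were -0.578, -0.882 and -0.523, all below the bound of -0.3 set beforehand, but the interval of the last, -1.04 to -0.115, reached past it and holds no spread between animals. Within run 1 the median was -0.55 (-1.36 to -0.332), so a run difference is unlikely to account for it. A first test, on the median nearest to 0 of both runs, gave a smaller shift (-0.284, -1.36 to -0.0485). Its interval excluded 0 but came nearer to it. Whether PGF2alpha or unrecorded differences between the animals lowered these genes was not tested.

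The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05, and the real split was the 1 with as many calls for each result. The real counts were 1351 probe sets, 799 at 2-fold, 606 genes and 12 lists, and the highest of the other splits gave 0, 0, 0 and 8.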
